A study of Rattus norvegicus with 18 samples.

How the data were processed

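Small RNA was sequenced from rat heart tissue in 18 libraries, 6 from each of 3 groups. The groups were Wistar Kyoto rats (WKY, given as normal), spontaneously hypertensive rats (SHR, given as hypertension) and SHR that received QDG (given as QDG treatment). Group and replicate number came from the library titles. The design text gives 6 animals per group and says that SHR received either NS or QDG. Neither abbreviation is spelled out in the sources used here. The labels do not say separately that each library came from a different rat, and if some did not, the p-values would measure only the spread between these libraries, part of which may be technical.

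Per the labels' protocols, total RNA was taken up in Trizol, its integrity was read on a Bioanalyzer, and libraries were made from 1 µg of it with the NEBNext Multiplex Small RNA kit. The submitters' processing notes name FastQC, TopHat2 and limma, with neither versions nor roles. The genome build and the miRNA annotation are not given in the sources used here. Per the file headers, the deposited values are normalized read counts, treated here as a signal per mature miRNA for 599 rat miRNAs. In each library the values were whole multiples of a single step, and 1000000 divided by that step was itself a whole number of reads. The authors thus appear to have divided each miRNA's reads by a number of reads particular to the library and scaled the result to reads per 1000000 (RPM). Read back with that step, 10782 of 10782 values lay within 0.01 of a whole read. They sum to more than 1000000 in each library, since the reads over all miRNAs exceed that divisor. How the authors counted reads that fit several miRNAs is not given in the sources used here, and entries with near-identical sequences are therefore uncertain. Rows that shared nearly all their reads were let-7a-1-3p with let-7c-2-3p and miR-466b-2-3p with miR-466b-4-3p, the latter pair being identical in 18 of 18 libraries.

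The tests planned before the data were examined assumed whole-number counts, with edgeR as the test, and named limma as the replacement for normalized values. That replacement was used. miRNAs with at least 1 RPM in at least 6 libraries were kept, which left 410 of 599. This filter was set after the unit was known and before any test. The values were taken as log2(RPM + 1) and limma (3.58.1, in R 4.3.3) was fitted to all 18 libraries with a trend in the variance and robust moderation, with no covariate. A fold change is therefore on the scale of RPM plus a pseudocount of 1 and understates the change of scarce miRNAs. Adjusted p-values are limma's, adjusted by Benjamini-Hochberg with a threshold of 0.05, and log2 fold changes are given ± their standard error (SE). Counts of libraries in the direction of a change are of those beyond the other group's mean, so single libraries can still overlap. On the recovered reads, edgeR (4.0.16, quasi-likelihood test), DESeq2 (1.42.0) and limma-voom were run as alternatives.

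The planned rule for the miRNAs named per comparison took those with an adjusted p under 0.05 and a mean of at least 10 RPM, up to 12 with the largest rise and up to 12 with the largest fall. Where none passed, it took the 10 with the smallest unadjusted p. It added the 10 most abundant miRNAs, the cardiac and muscle, miR-29, miR-132 with miR-212, miR-199 with miR-214 and red blood cell lists, and up to 4 members of each list called by camera. In all, 25 lists of miRNAs were fixed before the data were examined: cardiac and muscle miRNAs, miRNAs reported to promote or to restrain cardiac hypertrophy, the same for cardiac fibrosis, the let-7, miR-29, miR-30, miR-15/16, miR-34 with miR-449 and miR-132 with miR-212 families, the miR-17-92, miR-221 with miR-222, miR-199 with miR-214 and Dlk1-Dio3 clusters, and markers of vascular smooth muscle, endothelium, leukocytes, red blood cells, platelets with neutrophils, neurons, skeletal muscle, epithelium, liver and hypoxia. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The same test with a correlation estimated from the data and fry were run beside it. Counts of changed members are given over all 410 miRNAs and adjusted over the list alone. Some lists share members, so their calls are not independent.

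Single values per library were compared with two-sided exact permutation tests of 6 against 6 libraries, in which the smallest p possible is 0.00216. The SHR libraries enter SHR against WKY and QDG against SHR with opposite signs, so the correlation of these comparisons was set beside 10000 simulations with no effect and repeated over 20 splits of the SHR libraries into sets of 3. The WKY libraries were treated alike for the relation of SHR against WKY to QDG against WKY. The limma and list tests were tested on simulated data, drawn from the means and depths of these libraries, in 10 simulations with 200 of the listed miRNAs changed. Shares recovered are of the changed miRNAs that passed the filter. Those that the filter removed are left out, so the share of all changed miRNAs was lower. For SHR against WKY, limma recovered 70.8% of 1.5-fold (255 of 360) and 87.8% of 2-fold changes (289 of 329), and 2.86% of its calls were false. For QDG against SHR it recovered 69.2% of 1.5-fold (238 of 344) and 84.0% of 2-fold changes (284 of 338), and 2.83% of its calls were false. A 1.5-fold shift of the Dlk1-Dio3 list was found in 10 of 10 simulations, and 1 of 220 tests of unmoved lists was called. These simulations drew each miRNA independently, so they do not give the rate of false list calls among real miRNAs, which correlate.

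Alternatives covered the scaling (TMM, RLE, upper quartile, total count, and leaving out the 10 most abundant miRNAs), the filter, the pseudocount, the threshold, the libraries in the fit, the replicate number as a block and each library left out in turn. Chosen after seeing the data were edgeR on the recovered reads, TMM scaling, the list directions under each scaling, 10000 simulations with no effect in place of 100, the simulated and split overlap of calls against WKY, and leaving out WKY replicate 1 with SHR replicate 5, which stood apart on later principal components. Figures and single-value tests were made in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Which miRNA genes neighbour each other was read from a RefSeq gene table of the rat assembly GRCr8, whose names matched 560 of the 599 miRNAs; no coordinates are given, because the authors' build is not known. Within groups, 45 pairs of libraries were compared. None held identical values and the closest pair differed with a chi-square of 45.5 per degree of freedom, so all 18 were kept as separate libraries.

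The recovered reads over miRNAs numbered 6420666 to 10169581 per library and the divisors 4449279 to 7403775 reads. A single read was worth 0.135 to 0.225 RPM, and a floor of 3 reads, the limit that a count of 0 allows, 0.405 to 0.674 RPM. Intervals and floors cover counting error only, since amplified reads are not independent molecules. Reads outside the listed miRNAs, target genes and matched messenger RNA were not analysed here.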

Results

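miRNA levels in the heart were measured in 18 libraries, 6 each from WKY rats, the normotensive reference strain, from SHR, a strain that develops high blood pressure, and from SHR given QDG. Reads over miRNAs averaged 7653999 ± 1151748 in WKY, 7965255 ± 1257982 in SHR and 7726116 ± 709284 in QDG (SD, n = 6 each). The heart libraries were dominated by miR-1b, an entry of the muscle miR-1 family, with 27.5 ± 2.86% of reads in WKY, 26.1 ± 1.42% in SHR and 25.1 ± 1.06% in QDG. The 10 most abundant miRNAs together held 65.6 ± 1.28%, 65.7 ± 1.37% and 65.2 ± 0.416% of reads. Besides miR-1b they were miR-126a-3p, an endothelial miRNA, miR-1-3p, miR-133a-3p, another muscle miRNA, miR-143-3p of smooth muscle, and miR-26a-5p, miR-99a-5p, miR-30a-5p, miR-30c-5p and let-7g-5p. No difference in depth or in this share was detected between SHR and WKY (exact permutation p = 0.656 and 0.896), QDG and SHR (exact permutation p = 0.723 and 0.359) or QDG and WKY (exact permutation p = 0.892 and 0.591). miRNAs with at least 1 read numbered 505.5 ± 5.61 in WKY, 503 ± 11.2 in SHR and 497 ± 4.88 in QDG. Of these counts only QDG against WKY, a difference of -8.67, had a small unadjusted p (exact permutation p = 0.0216), which was 0.195 after adjustment over the 9 composition tests.

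The WKY libraries lay apart from the SHR and QDG libraries along the first principal component, which held 29.9% of the variance. WKY libraries lay between -5.87 and -4.39, SHR libraries between 1.32 and 3.60 and QDG libraries between 1.24 and 3.57. SHR and QDG each differed from WKY along it (exact permutation p = 0.00216 for each, the smallest possible), while no difference between QDG and SHR was detected (exact permutation p = 0.658). On the second component (13.8%) SHR replicate 5 stood apart at -7.58, and on the third (9.76%) WKY replicate 1 at 6.25.

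**Figure D1:**
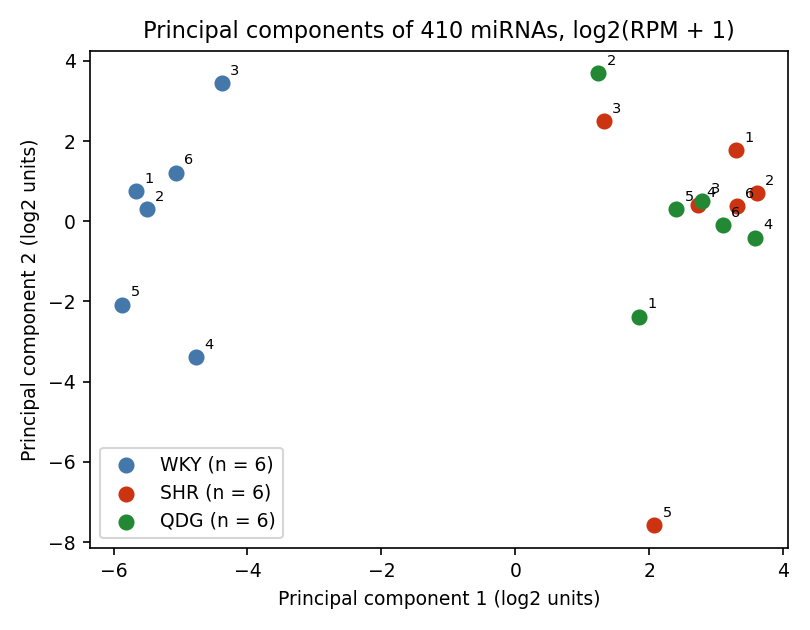
Principal components of log2(RPM + 1) over the 410 tested miRNAs, with each point 1 library, colored by group. The axes are component scores in log2 units. The 6 WKY libraries lie at or below -4.39 on the first component, and the SHR and QDG libraries overlap between 1.24 and 3.60.

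The first comparison, SHR against WKY, asks which heart miRNAs differ in the hypertensive strain. miR-208b-3p, encoded within the beta-myosin heavy chain gene, rose from 157 ± 41.2 to 288 ± 58.6 RPM (SD, n = 6 each). The abundant muscle miRNA miR-1-3p rose 1.67-fold, from 70589 ± 8617 to 117240 ± 10227 RPM (SD, n = 6 each). miR-34a-5p, a target of the tumour suppressor p53, rose 2.02-fold from 117 ± 15.4 to 236 ± 22.6 RPM (SD, n = 6 each), and miR-182 rose 3.94-fold from 6.74 ± 0.722 to 29.7 ± 4.60 RPM. In the other direction, miR-127-3p of the imprinted Dlk1-Dio3 locus fell from 147 ± 18.8 to 70.0 ± 15.3 RPM, 2.11-fold lower on the tested scale. In all, 95 of 410 miRNAs differed (33 higher and 62 lower, limma adjusted p under 0.05), 12 of them by at least 2-fold, and 42 miRNAs had no overlap between the 6 libraries of each group, which chance gives for 0.216% of miRNAs.

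Among miRNAs of at least 10 RPM, the largest rises on the log2 scale were 1.98 ± 0.18 for miR-182 (SE, adjusted p = 6.86e-09) and 1.49 ± 0.16 for miR-190b-5p (adjusted p = 3.34e-08), followed by miR-34a-5p at 1.02 ± 0.10 (adjusted p = 1.09e-08) and miR-452-5p at 0.92 ± 0.16 (adjusted p = 0.000118). miR-208b-3p had 0.89 ± 0.16 (adjusted p = 0.000132), miR-132-5p 0.81 ± 0.17 (adjusted p = 0.000687) and miR-1-3p 0.74 ± 0.08 (adjusted p = 3.34e-08). miR-132-3p, miR-708-5p, miR-484, miR-146b-5p and miR-331-3p rose by 0.51 to 0.70. Their adjusted p lay between 0.000114 and 0.0308. The largest falls were -1.15 ± 0.18 for miR-34b-5p (adjusted p = 2.3e-05), -1.09 ± 0.19 for miR-379-5p (adjusted p = 0.000114), -1.07 ± 0.13 for miR-127-3p (adjusted p = 2.62e-07) and -1.06 ± 0.11 for miR-598-3p (adjusted p = 3.34e-08). miR-411-5p, miR-34c-5p, miR-547-5p and miR-490-5p had changes of -0.90 to -0.68. miR-351-5p fell from 377 ± 54.5 to 243 ± 25.3 RPM and miR-210-3p, a miRNA induced by hypoxia, from 394 ± 63.6 to 271 ± 14.1 RPM (log2 -0.62 and -0.52), and miR-1843a-5p and miR-201-5p had -0.51 and -0.45. For each of these changes, 6 of 6 SHR libraries lay on the stated side of the WKY mean. The calls of miR-484, miR-146b-5p and miR-201-5p were the weak ones: miR-484 was lost without WKY replicate 1 (adjusted p = 0.0934), WKY replicate 6 (0.0655), SHR replicate 1 (0.0703), SHR replicate 3 (0.0686) or SHR replicate 6 (0.0636), miR-201-5p without WKY replicate 5 (adjusted p = 0.0532), and miR-146b-5p without WKY replicate 1 and SHR replicate 5 together (adjusted p = 0.0533).

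**Figure D2:**
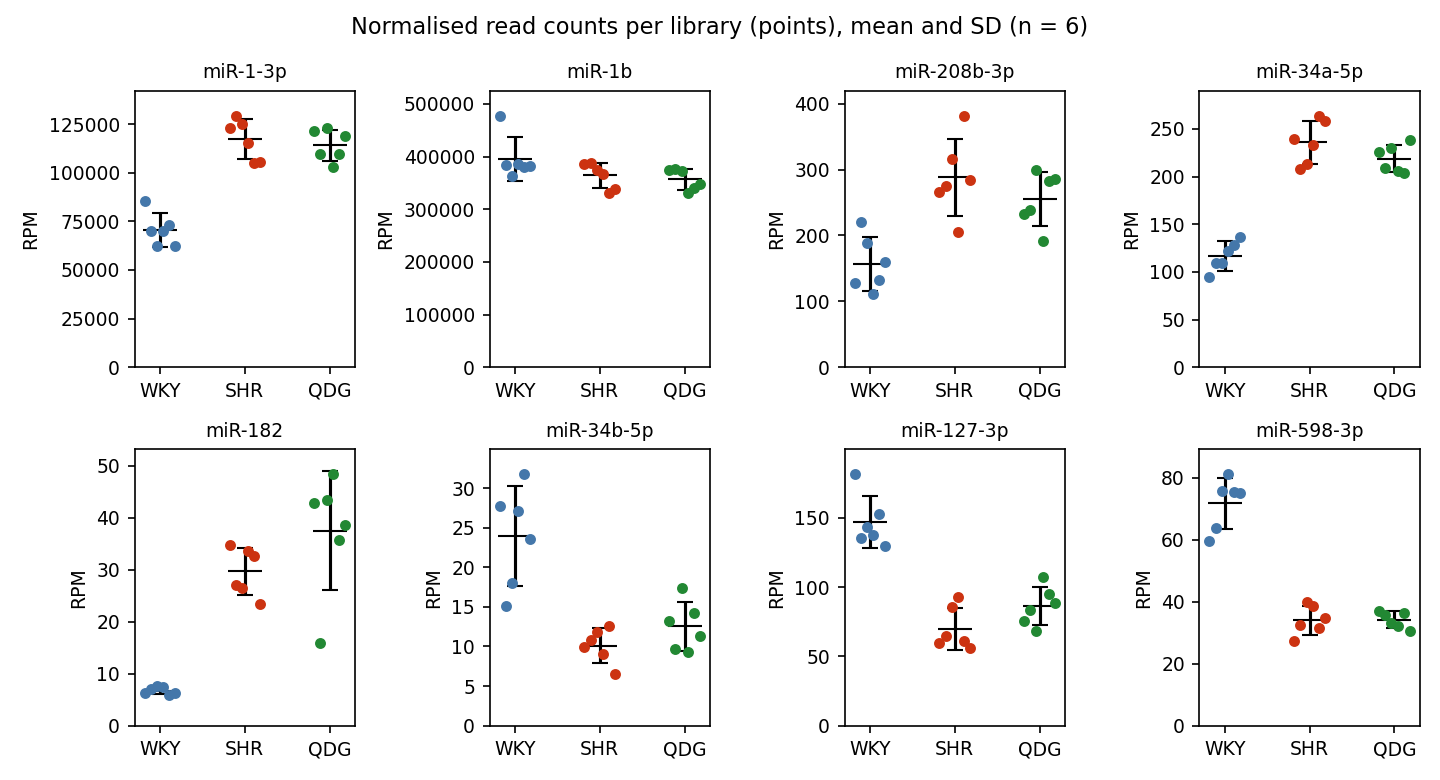
Levels in RPM, on axes that start at 0, of 8 miRNAs in the 3 groups; points are libraries, and the bars give the mean and SD of 6 libraries per group. miR-1-3p, miR-208b-3p, miR-34a-5p and miR-182 lie higher in SHR and QDG than in WKY, miR-34b-5p, miR-127-3p and miR-598-3p lower, and miR-1b does not pass the test (adjusted p = 0.243 for SHR against WKY).

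Of 11 cardiac and muscle entries, only miR-1-3p and miR-208b-3p changed. miR-1b had 395414 ± 41175 RPM in WKY and 363996 ± 24176 RPM in SHR (log2 -0.12 ± 0.07, adjusted p = 0.243). miR-1b and miR-1-3p belong to one family, and reads that fit both are of uncertain origin, since how the authors counted them is not given in the sources used here. miR-133a-3p had -0.01 ± 0.13, miR-133a-5p 0.04, miR-133b-3p -0.33, miR-206-3p, the skeletal muscle marker, -0.33, miR-208a-3p -0.16, miR-208a-5p -0.20, miR-499-5p -0.19, miR-499-3p -0.11 and miR-486 -0.03, with adjusted p from 0.0698 to 0.949. Without WKY replicate 1, which had the highest miR-1b share (33.1%), miR-133b-3p passed with -0.47, miR-208a-3p with -0.28 and miR-208a-5p with -0.32 (adjusted p = 0.0144, 0.0342 and 0.0455). miR-206-3p passed without WKY replicate 2 (adjusted p = 0.0367) or SHR replicate 1 (0.0141). The list as a whole was not called (camera adjusted p = 0.615), and its median of -0.11 (-0.07 to -0.01 under the 5 other scalings, -0.21 to -0.02 with 1 library left out) and mean of 0.03 differed in sign. Of the other abundant miRNAs, miR-99a-5p fell (-0.42 ± 0.08, adjusted p = 0.000233, 6 of 6 libraries). miR-126a-3p (0.09), miR-26a-5p (-0.19), miR-143-3p (-0.24) and miR-30c-5p (-0.11) had adjusted p of 0.0524 to 0.406; miR-26a-5p passed without WKY replicate 1, SHR replicate 1 or SHR replicate 6 (adjusted p = 0.0351, 0.0455 and 0.0470), miR-143-3p without WKY replicate 2 or SHR replicate 6 (0.0366 and 0.0473), and miR-126a-3p under TMM scaling (0.20, adjusted p = 0.0462).

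Of miRNAs reported to promote cardiac hypertrophy, 6 of 23 members were higher and 0 lower (median 0.14, camera adjusted p = 0.00348, 6 members adjusted over the list alone). The list had adjusted p = 0.697 with an estimated correlation, and fry, which tests it in one direction against no change, did not call it (adjusted p = 0.158). The risers were miR-208b-3p, miR-132-5p, miR-132-3p, miR-212-5p, miR-21-5p and miR-221-3p, the last chosen after its values were seen. Of these, miR-132-5p, miR-132-3p and miR-212-5p also belong to the list of miR-132 with miR-212, and miR-21-5p to the fibrosis list. The calls of these lists are therefore not separate findings. miR-21-5p, abundant in fibroblasts, rose from 17299 ± 980.3 to 23706 ± 6058 RPM (log2 0.42 ± 0.11, adjusted p = 0.00513), and miR-21-3p had 0.51 ± 0.24 (adjusted p = 0.126), passing without SHR replicate 3 (0.66, adjusted p = 0.0358). The miR-132 and miR-212 family, whose precursors lie side by side and respond to the factor CREB, had 3 of 4 members higher and 4 adjusted over the list alone (median 0.67, camera adjusted p = 0.00733). That call had adjusted p = 0.642 with an estimated correlation. miR-212-5p had 0.64 ± 0.20 (adjusted p = 0.0192), lost without SHR replicate 1 (0.0565) or SHR replicate 5 (0.0604), and miR-212-3p had 0.54 ± 0.25 (adjusted p = 0.121), passing without SHR replicate 3 (0.69, adjusted p = 0.0387). In the list reported to promote fibrosis, 3 of 8 members rose and 0 fell (3 adjusted over the list alone, median 0.32, camera adjusted p = 0.0166), with adjusted p = 0.642 with an estimated correlation. They were miR-34a-5p, miR-21-5p and miR-155-5p, a miRNA of activated immune cells (0.48 ± 0.14, adjusted p = 0.0128). Under the 5 other scalings 6 to 9, 3, and 3 to 4 members of these lists were called, in that order, and the medians were 0.18 to 0.24, 0.67 to 0.75 and 0.36 to 0.42. With 1 library left out the medians were 0.08 to 0.18, 0.50 to 0.75 and 0.22 to 0.36.

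The list with the most lower members was the Dlk1-Dio3 cluster, a large imprinted miRNA locus expressed from the maternal allele: 17 of 34 fell and 0 rose, 21 fell adjusted over the list alone, and the median was -0.52 (camera adjusted p = 3.15e-06). The call had adjusted p = 0.642 with an estimated correlation. Besides miR-127-3p, miR-379-5p and miR-411-5p, the named members miR-494-3p and miR-541-5p fell, with log2 changes of -1.10 and -0.99 (adjusted p = 8.28e-05 and 0.000124, 6 of 6 libraries each). In the let-7 family, miRNAs linked to differentiation, 8 of 21 members fell and 9 adjusted over the list alone (median -0.21, camera adjusted p = 0.00733; adjusted p = 0.642 with an estimated correlation). let-7d-5p, let-7e-5p and let-7a-5p had -0.44 ± 0.09, -0.43 ± 0.08 and -0.41 ± 0.07 (adjusted p = 0.000326, 0.000209 and 5.36e-05), while the calls of let-7f-2-3p (-0.40, adjusted p = 0.0179) and let-7g-5p (-0.21, adjusted p = 0.022) were lost without SHR replicate 4 (0.0524) and without WKY replicate 4 (0.0553), respectively, and that of let-7g-5p under 4 of the 5 other scalings (0.203 to 0.306). In the miR-30 family, abundant in heart muscle cells, 6 of 11 fell and 7 adjusted over the list alone (median -0.25, camera adjusted p = 0.0158; adjusted p = 0.642 with an estimated correlation). Under the 5 other scalings the medians shrank to between -0.16 and -0.11 for let-7 and between -0.20 and -0.15 for miR-30, with 5 to 6 and 1 to 2 members called. With 1 library left out they were -0.25 to -0.13 and -0.27 to -0.20. Under TMM the miR-30 list had a camera adjusted p of 0.0512. How reads that fit several let-7 or several miR-30 entries were counted is not given in the sources used here. Members of these families may thus share reads, and in each comparison their counts may not be separate evidence. miR-30c-1-3p (-0.45 ± 0.11, adjusted p = 0.00309) was called under each scaling. miR-30b-5p, miR-30e-5p, miR-30d-3p and miR-30a-5p had -0.30, -0.28, -0.25 and -0.20 (adjusted p of 0.0204 to 0.0411), and each lost its call under TMM (0.0748, 0.0972, 0.198 and 0.280). With a single library left out, miR-30e-5p lost its call without WKY replicate 5 (0.0680) or SHR replicate 4 (0.0506), and miR-30a-5p without WKY replicate 4 (0.0501) or 5 (0.0921) or SHR replicate 1 (0.0621), 3 (0.0520) or 4 (0.0755). miR-30b-5p did so without WKY replicate 4 (0.0553), 5 (0.102) or 6 (0.0621) or SHR replicate 1 (0.0504), 2 (0.0601), 4 (0.0608) or 6 (0.0636), and miR-30d-3p without WKY replicate 5 (0.107) or 6 (0.0740) or SHR replicate 1 (0.0703), 2 (0.0805), 3 (0.0596), 5 (0.0756) or 6 (0.0533).

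Lists that camera did not call held changed members too. In the family of miR-34 and miR-449 all 6 tested members changed, 2 up and 4 down (6 adjusted over the list alone, camera adjusted p = 0.614): miR-34a-5p rose while miR-34b-5p and miR-34c-5p fell, the latter by 0.79 on the log2 scale (adjusted p = 8.28e-05). Among miRNAs reported to restrain hypertrophy, 3 of 29 rose and 7 fell, 11 changed adjusted over the list alone, and the camera adjusted p was 0.423. The risers were miR-1-3p, miR-378a-3p and miR-378a-5p, of which miR-1-3p is known for repressing growth of heart muscle cells and the miR-378a pair for its host gene, a regulator of mitochondrial metabolism. miR-378a-5p was chosen after its values were seen. For miRNAs reported to restrain fibrosis, 4 of 21 fell (4 adjusted over the list alone, camera adjusted p = 0.443). The miR-29 family, which represses collagen messages, had 2 of 6 members lower (2 adjusted over the list alone, camera adjusted p = 0.443): miR-29b-3p with -0.40 ± 0.11 (adjusted p = 0.00711) and miR-29c-5p with -0.29 ± 0.10 (adjusted p = 0.0373), whose call was lost under all 5 other scalings (adjusted p = 0.0707 to 0.138) and without any of 7 single libraries, WKY replicates 2 (0.0502), 5 (0.0995) and 6 (0.101) and SHR replicates 1 (0.0621), 2 (0.0735), 3 (0.0520) and 5 (0.0828). miR-29a-3p had -0.08 and miR-29c-3p -0.21 (adjusted p = 0.624 and 0.237), miR-29b-5p -0.31 (adjusted p = 0.106; 0.0417 without WKY replicate 1) and miR-29a-5p 0.20 (adjusted p = 0.270; 0.0462 under TMM, with 0.29).

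Among markers of other cell types and the remaining lists, the red blood cell miRNAs miR-144-3p, miR-144-5p and miR-451-5p had 0.03, 0.02 and 0.14, with 0 of 4 called (0 adjusted over the list alone, camera adjusted p = 0.662). The miR-199 and miR-214 cluster of fibroblasts and smooth muscle had 0 of 3 called (0 adjusted over the list alone, camera adjusted p = 0.614), with miR-199a-3p at 0.03, miR-199a-5p at 0.13 and miR-214-3p at 0.08. Of 18 leukocyte miRNAs 3 rose (3 adjusted over the list alone, camera adjusted p = 0.662), namely miR-155-5p, miR-146b-5p and miR-146b-3p. Of 12 endothelial miRNAs miR-130a-3p and miR-221-3p rose and miR-210-3p fell (3 adjusted over the list alone, camera adjusted p = 0.666). Of 12 neuronal miRNAs miR-218a-5p and miR-219a-1-3p rose and miR-129-5p fell (3 adjusted over the list alone, camera adjusted p = 0.443). Of 8 epithelial miRNAs miR-200c-3p rose (1 adjusted over the list alone, camera adjusted p = 0.662), as did miR-221-3p of 3 in the miR-221 and miR-222 cluster (1 adjusted over the list alone, camera adjusted p = 0.251), and in the miR-15/16 family 1 of 10 fell, miR-322-3p (1 adjusted over the list alone, camera adjusted p = 0.925). These members, apart from miR-155-5p, miR-146b-5p and miR-210-3p, were chosen after their values were seen. None of the tested members passed in limma in the lists of 4 vascular smooth muscle, 6 platelet and neutrophil, 3 liver and 19 miR-17-92 miRNAs, with 0 adjusted over the list alone in each (camera adjusted p = 0.662, 0.443, 0.654 and 0.558). Skeletal muscle, with miR-206-3p alone, and hypoxia, with the arms of miR-210, were too short for a list test: 0 of 1 passed (1 adjusted over the list alone) and 1 of 2 fell (2 adjusted over the list alone).

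Strain, blood pressure and what else was given to the animals cannot be told apart in this comparison, since each group holds 1 strain and 1 condition. Any handling of the samples that followed group cannot be told apart from them either. The balance of higher and lower miRNAs depended on the scaling: 34.7% of calls were higher with the authors' values, 48.9% with RLE (45 higher, 47 lower), 46.6% with upper quartile scaling (41 and 47), 47.3% with the 10 most abundant miRNAs left out of the scaling (43 and 48) and 54.7% with TMM (52 and 43).

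The next comparison, QDG against SHR, asks whether QDG changed heart miRNAs within the SHR strain. No single miRNA passed the threshold. Of the Dlk1-Dio3 cluster, 33 of 34 members lay on the higher side in QDG (median log2 0.24). The list test called this at its preset correlation but not with an estimated one (camera adjusted p = 4.66e-09 and 0.440), and fry did not (0.609). miR-127-3p had 70.0 ± 15.3 RPM in SHR and 86.4 ± 13.96 RPM in QDG. Of the miRNAs that differed between strains, miR-182 had 29.7 ± 4.60 RPM in SHR and 37.5 ± 11.5 RPM in QDG, miR-208b-3p 288 ± 58.6 and 255 ± 41.2 RPM, and miR-1-3p 117240 ± 10227 and 114140 ± 7938 RPM (SD, n = 6 each).

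limma called 0 of 410 miRNAs, with 15 at an unadjusted p under 0.05 and a smallest adjusted p of 0.189. On the recovered reads edgeR, DESeq2 and limma-voom called 0 of 361 each, with 13, 15 and 15 at an unadjusted p under 0.05. Each of these counts is below what that threshold gives on average by chance alone. On the scale of RPM + 1, the 95% confidence interval of the change lay within 2-fold for 402 of 410 miRNAs and within 1.5-fold for 333. For those of at least 10 RPM it lay within 2-fold for 249 of 249 and within 1.5-fold for 238. For scarcer miRNAs the pseudocount narrows the interval, so it does not bound the change in their level. The 10 miRNAs with the smallest unadjusted p did not pass. They were led by 2 scarce Dlk1-Dio3 members, miR-136-3p (0.67 ± 0.17, 1.72 ± 0.665 RPM in SHR and 3.26 ± 0.685 RPM in QDG) and miR-376b-3p (0.73 ± 0.20, 0.404 ± 0.434 and 1.26 ± 0.332 RPM), with limma unadjusted p of 0.000682 and 0.000921 and an adjusted p of 0.189 for both. Values of both lay above the SHR mean in 6 of 6 QDG libraries, but 0 of 410 miRNAs were free of overlap between QDG and SHR libraries. miR-202-5p had -0.99 ± 0.33 (adjusted p = 0.977), and its SHR mean rested on SHR replicate 2 at 8.21 RPM, the next SHR library having 1.57 RPM. miR-148a-5p (0.26), miR-92b-3p (-0.47), miR-378b (0.23), miR-341 (0.37), miR-127-3p (0.31), miR-449a-5p (-0.45) and miR-183-5p (0.38) all had an adjusted p of 0.983.

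The Dlk1-Dio3 list was the 1 list that the preset-correlation test called, with 0 members over all miRNAs and 2 adjusted over the list alone, and adjusted p = 0.440 with an estimated correlation. Its mean log2 level per library was 2.23 ± 0.09 in WKY, 1.70 ± 0.25 in SHR and 1.94 ± 0.11 in QDG (SD, n = 6 each; exact permutation p = 0.0628 for QDG against SHR and 0.00216 for each against WKY). The other lists with 3 or more tested members had 0 members called in limma, 0 adjusted over the list alone, and camera adjusted p of 0.227 to 0.881, among them miRNAs reported to promote hypertrophy (0.709) or fibrosis (0.773), let-7 (0.605), miR-30 (0.227) and the family of miR-132 and miR-212 (0.483). Members of the cardiac and muscle, miR-29, miR-132 with miR-212, miR-199 with miR-214 and red blood cell lists had log2 changes of -0.20 to 0.18, each with an adjusted p of 0.983 or 0.986.

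**Figure D3:**
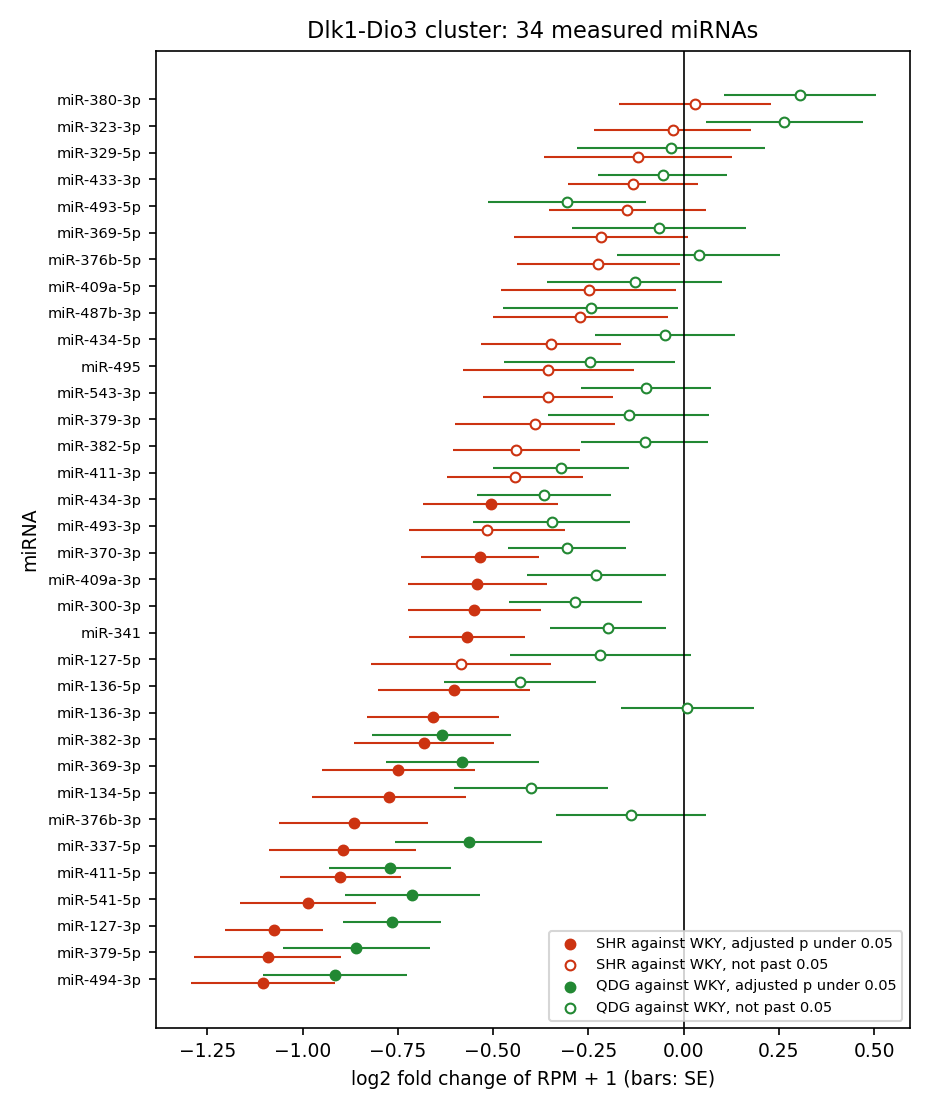
log2 fold change with its SE for each of the 34 tested Dlk1-Dio3 members, SHR against WKY and QDG against WKY; filled symbols have an adjusted p under 0.05. Of the members, 17 are filled for SHR and 8 for QDG, all below 0.

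Across the 410 miRNAs, the changes SHR against WKY and QDG against SHR correlated with r = -0.26. Simulations with no effect that shared the SHR libraries gave a mean of -0.49 (-0.75 to -0.18 for the middle 95% of 10000 simulations), and 93.1% were at least as negative. They also lacked the strain difference, which widens the changes of SHR against WKY and draws r toward 0. That share therefore cannot decide whether QDG opposed the strain difference. Runs of 100 simulations, as first used, gave 87 to 100 as negative over 10 seeds. With the SHR libraries split into sets of 3, so that the comparisons shared none, r averaged -0.01 (-0.15 to 0.08 over 20 splits). The covariance was -0.0177 beside a mean of -0.0152 in the simulations, a difference of -0.00249. No range was taken for it, so it does not decide the question either. Genes are not independent replicates here. Of the 95 miRNAs called between strains, 72 had the opposite sign in QDG against SHR and 6 had an unadjusted p under 0.05 there. None passed in both comparisons, since limma, edgeR, DESeq2 and limma-voom called 0 in QDG against SHR (15, 13, 15 and 15 at an unadjusted p under 0.05). Among miRNAs called with one part of the SHR libraries, 59.2% (50 to 70.6%) had the opposite sign against the other part, with a median change of -0.03 along the strain direction beside 0.58 for SHR.

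The last comparison, QDG against WKY, shows how far hearts of treated SHR lay from the reference strain. Again miR-182 (2.24 ± 0.18, 37.5 ± 11.5 RPM), miR-34a-5p (0.91 ± 0.10), miR-208b-3p (0.72 ± 0.16, 255 ± 41.2 RPM) and miR-1-3p (0.70 ± 0.08, 114140 ± 7938 RPM) rose. miR-598-3p (-1.04 ± 0.11), miR-34b-5p (-0.87 ± 0.18) and miR-127-3p (-0.76 ± 0.13) fell. The energy-metabolism miRNA miR-378a-3p rose from 23547 ± 2775 RPM to 34918 ± 3849 RPM (0.57 ± 0.09). In all, limma called 73 of 410, 30 higher and 43 lower, 8 of them by at least 2-fold, and 33 miRNAs had no overlap between groups.

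Adjusted p were 3.79e-10 for miR-182, 4.65e-08 for miR-34a-5p and miR-598-3p, 0.00136 for miR-208b-3p, 9.46e-08 for miR-1-3p, 7.36e-05 for miR-127-3p and 3.11e-05 for miR-378a-3p, with the direction in 6 of 6 QDG libraries for each. Of the other largest rises, miR-190b-5p had 1.37 ± 0.16, and miR-452-5p, miR-132-5p, miR-132-3p, miR-708-5p, miR-331-3p and miR-146b-5p had 0.54 to 0.82. Of the other largest falls, miR-379-5p had -0.86, and miR-411-5p, miR-547-5p, miR-34c-5p, miR-351-5p, miR-490-5p, miR-210-3p, miR-1839-5p and miR-3585-5p had -0.77 to -0.50. miR-29b-3p fell by 0.39 on the log2 scale (adjusted p = 0.0102). miR-99a-5p had -0.28 (adjusted p = 0.0109), a call lost under TMM (0.108), RLE (0.0533) and upper quartile scaling (0.0907) and with the 10 most abundant miRNAs left out of the scaling (0.0625).

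Called lists, each with adjusted p = 0.865 with an estimated correlation, were those reported to promote hypertrophy (4 of 23 higher, 4 adjusted over the list alone, camera adjusted p = 0.00895) and, at a camera adjusted p of 0.0213 each, fibrosis (3 of 8 higher, 4 adjusted over the list alone), miR-132 with miR-212 (2 of 4 higher, 3 adjusted over the list alone), let-7 (5 of 21 lower, 5 adjusted over the list alone) and Dlk1-Dio3 (8 of 34 lower, 8 adjusted over the list alone, median -0.24). In one direction fry did not call the hypertrophy list (adjusted p = 0.173). It shares members with the fibrosis list and with that of miR-132 and miR-212, so these calls are not separate findings. Without WKY replicate 1 the Dlk1-Dio3 and fibrosis lists had a camera adjusted p of 0.20 and 0.0508. Members that rose were miR-21-5p (0.43 ± 0.11, adjusted p = 0.00436) and miR-155-5p (0.41 ± 0.14, adjusted p = 0.0422), the latter lost without WKY replicate 1 (0.0543), 2 (0.0837), 3 (0.0954) or 6 (0.0786) or QDG replicate 1 (0.0534), 3 (0.0692), 5 (0.120) or 6 (0.119). Members that fell were let-7d-5p (-0.45), let-7a-5p (-0.38), let-7e-5p (-0.35), let-7f-2-3p (-0.37) and miR-494-3p (-0.91), of which let-7f-2-3p was lost under TMM (0.0578) and without WKY replicate 2 (0.0656), 5 (0.0804) or 6 (0.0527) or QDG replicate 1 (0.0505), 2 (0.0512), 4 (0.0780) or 6 (0.0575). The other cardiac and muscle entries, miR-29 members (from -0.25 to 0.29), miR-212 arms (0.45 and 0.44), miR-199 and miR-214 (0.01 to 0.14) and red blood cell miRNAs (-0.08 to 0.22) did not pass. Of these, miR-29a-5p (0.29, adjusted p = 0.0977) passed as higher under RLE (0.0235), upper quartile (0.0304) and TMM scaling (0.0129), with the 10 most abundant miRNAs left out of the scaling (0.0242) and without WKY replicate 2 (0.0462). It also passed on the recovered reads by edgeR, DESeq2 and limma-voom. miR-29c-3p (-0.25, adjusted p = 0.155) passed as lower without WKY replicate 1 (0.0369). The remaining lists had camera adjusted p of 0.118 to 0.897, including miR-30 (1 of 11 lower, 1 adjusted over the list alone, 0.118). The share of higher calls was 41.1% with the authors' values, 51.2% with RLE (42 higher, 40 lower), 52.5% with the 10 most abundant miRNAs left out of the scaling (42 and 38) and 61.0% with TMM (50 and 32).

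Calls against WKY were compared next. Of 33 miRNAs higher in SHR and 30 higher in QDG, 25 were shared, and of 62 and 43 lower, 38, beside 2.41 and 6.50 for independent lists. Since both use the WKY libraries, simulations with no effect that shared them were ranked by p into lists of the same sizes. These shared 9.23 (1 to 25) higher and 17.6 (3 to 31) lower miRNAs over 100 simulations. The observed 25 lay at the top of the simulated range, and the observed 38 above it. With the WKY libraries split into sets of 3, so that the comparisons shared none, 13.9 higher calls (11 to 16) and 19.8 lower ones (17 to 23) were in both, beside 1.26 and 2.999 for independent lists. These came from shorter lists, on average 21 and 22.35 higher and 40.75 and 28.4 lower calls in SHR and QDG. Ranked by p into lists of the full sizes, the split comparisons shared 20.75 (18 to 23) higher and 30.7 (28 to 34) lower miRNAs. The fold changes correlated with r = 0.91, beside 0.49 (0.16 to 0.74 for the middle 95% of 10000) in simulations with no effect that shared the WKY libraries, and 0.76 (0.72 to 0.81) over 20 splits of the WKY libraries into sets of 3. The covariance was 0.141 beside 0.0152 simulated, a difference of 0.126. Of the 95 miRNAs called in SHR, 94 had the same sign in QDG, 32 were called in SHR alone and 10 in QDG alone. Whether those calls differ between SHR and QDG is tested by QDG against SHR, in which limma called 0 (15 at an unadjusted p under 0.05, and 0 by edgeR, DESeq2 and limma-voom).

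**Figure D4:**
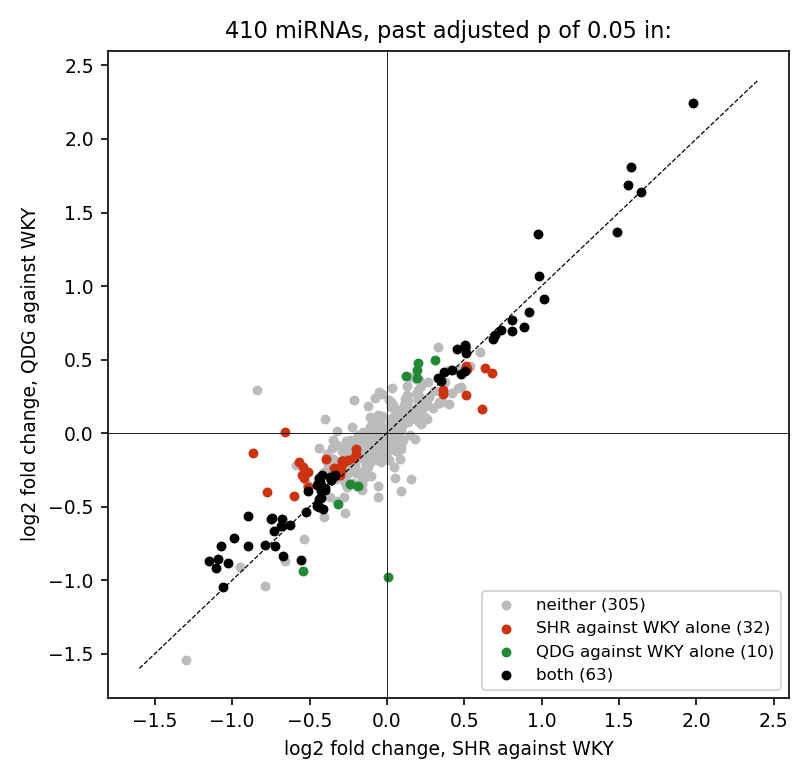
log2 fold change against WKY of each of the 410 tested miRNAs in SHR (x axis) and in QDG (y axis), colored by whether the miRNA was called in both (63), in SHR alone (32), in QDG alone (10) or in neither; the dashed line marks equal change. The called miRNAs lie along the line, with r = 0.91 over all miRNAs.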

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

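All tests of explanations in this part were chosen only after the results they bear on had been seen.

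A first pattern was the near absence of the miR-290 cluster, miRNAs of early embryonic cells, from WKY hearts: its 6 listed entries held 3 reads in WKY, 152 in SHR and 142 in QDG, or 0.0939 RPM (exact Poisson 95% interval 0.0194 to 0.274), 4.42 (3.75 to 5.19) and 4.35 (3.66 to 5.12), a ratio of 46.7 for both SHR groups over WKY. Deeper sequencing is argued against by the lower bound of that ratio, 15.8. Reads of a single other miRNA falling into 1 entry could account for much of the pattern, as miR-293-5p held 85 reads in SHR, 82 in QDG and all 3 in WKY. They would not account for miR-292-5p (31 in SHR, 21 in QDG, 0 in WKY) or miR-295-3p (18, 17 and 0). The remaining entries held fewer reads. That 4 of 6 entries had more than 3 reads in 3 or more SHR-strain libraries only just met a cut set with the values known, and decides nothing. Carry-over into single libraries is argued against by more than 3 cluster reads in 12 of 12 SHR-strain libraries (lowest 9). Handling or a shared source that followed strain stays open, as does a difference between strains in the locus or in a few cells, which may be the candidate explanation most worth testing on the genomes of both strains.

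A second pattern was that Dlk1-Dio3 members in QDG lay between SHR and WKY, at a summed level of 290 ± 26.2 RPM in WKY, 155 ± 38.3 in SHR and 191 ± 24.7 in QDG (SD, n = 6 each). The values decide neither technical explanation. Chance values of the SHR libraries, which both comparisons share, remain possible, since the cluster mean per library did not pass (exact permutation p = 0.0628), and so does noise of members with few reads, since the summed level did not pass either (exact permutation p = 0.0866). Of 4 such measures of the cluster, only its mean less that of the neuronal list, made for another question, had a small unadjusted p (exact permutation p = 0.0173). That measure takes in levels outside the cluster, and it was not the one set for this question. SHR replicates 3 and 4 had 199.8 and 208 RPM, inside the QDG range of 156 to 215 RPM. A partial effect of QDG on the locus may also account for it and is untested beyond these values.

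The last pattern was a rise of miR-1-3p with none detected for miR-1b, so that the log2 ratio of miR-1-3p to miR-1b was -2.49 ± 0.08 in WKY, -1.64 ± 0.04 in SHR and -1.65 ± 0.08 in QDG (exact permutation p = 0.00216, the smallest possible, for SHR against WKY, and 0.816 for QDG against SHR). The scaling is argued against by the smallest change of miR-1-3p over 5 other scalings, 0.78. Reads moved between the entries stay open, since their sum was 466003 ± 49030 RPM in WKY and 481236 ± 34140 in SHR (exact permutation p = 0.567). Such a move could come from a strain variant, from other read ends or from how reads fitting both were assigned, none of which the deposited values can test, and a difference between strains in miR-1 expression stays open too.

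Single libraries stood far from the others of their group for 20 of 258 sets of 6 values examined, where chance alone gives about 1 in 20, or 12.9. WKY replicate 1 was involved in 4: miR-1b at 477644 RPM (next 385672), miR-206-3p at 994 RPM (next 689), let-7d-5p lowest at 2797 RPM (next 3225), and the share of the 10 most abundant miRNAs at 68.1% (next 65.6%). SHR replicate 5 was highest for miR-132-3p at 24.1 RPM (next 13.04), miR-34c-5p at 96.4 RPM (next 57.8) and miR-199a-5p at 3428 RPM (next 2294). SHR replicate 4 was highest for miR-379-5p at 9.77 RPM (next 7.16) and miR-133a-5p at 2598 RPM (next 2399). QDG replicate 2 was highest for miR-547-5p at 23.1 RPM (next 15.3) and lowest for miR-351-5p at 192 RPM (next 244). QDG replicate 4 was highest for miR-143-3p at 70852 RPM (next 57856) and lowest for miR-29a-3p at 10399.6 RPM (next 13805). QDG replicate 5 was highest for miR-126a-3p at 126667 RPM (next 118342), and QDG replicate 1 had the most miRNAs detected, 506 (next 497). WKY replicate 4 was highest for miR-190b-5p at 8.28 RPM (next 4.42), and WKY replicate 3 lowest for miR-494-3p at 2.14 RPM (next 4.42). SHR replicate 1 was highest for miR-206-3p at 771 RPM (next 577), SHR replicate 2 for miR-202-5p at 8.21 RPM (next 1.57), and SHR replicate 3 lowest for miR-30c-1-3p at 59.7 RPM (next 65.6).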

How the results depend on the processing

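Chosen after the data were seen were edgeR on recovered reads, TMM scaling, the list directions under each scaling, 10000 simulations with no effect in place of 100, the simulated and split overlap of calls against WKY, and leaving out WKY replicate 1 with SHR replicate 5; the other alternatives were planned. The count of 95 miRNAs between SHR and WKY stayed within 1.5 times under each alternative except a 2-fold minimum, which left 12 by its construction, and the count of 73 between QDG and WKY likewise, with 8. For SHR against WKY, 76 of the 95 were also called under TMM, 80 under RLE, 80 by edgeR, 78 by DESeq2 and 82 by limma-voom. Leaving out 1 library gave 81 to 106 for SHR against WKY, 64 to 81 for QDG against WKY and 0 for QDG against SHR (limma, where 15 had an unadjusted p under 0.05 with all libraries). Without WKY replicate 1 and SHR replicate 5, 97 and 83 were called.

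Calls by camera rested on its preset correlation: with an estimated correlation 0 lists were called in each comparison. fry, which does not compare a list with other miRNAs, gave 13, 0 and 12 lists that changed in either direction for SHR against WKY, QDG against SHR and QDG against WKY, and 5, 0 and 5 in one direction. For SHR against WKY the 5 were Dlk1-Dio3 (fry adjusted p = 0.00133), let-7 and miR-30 (0.00228 each), and miR-132 with miR-212 and fibrosis (0.00801 each), without the hypertrophy list. For QDG against WKY they were fibrosis and let-7 (0.0226 each), miR-132 with miR-212 and miR-30 (0.0337 each) and Dlk1-Dio3 (0.0434), of which camera did not call miR-30. For the lists called between SHR and WKY the correlation was estimated at 0.208 (let-7) to 0.591 (miR-132 with miR-212), beside the preset 0.01. Its size was not all that differed between the camera runs. For the liver list, SHR against WKY, the estimate was negative (-0.311), yet the unadjusted camera p rose from 0.483 to 0.490. The loss of list calls therefore cannot be put down to the correlation alone.

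The difference in miRNAs detected between QDG and SHR ranged from -9.77 (without SHR replicate 1, exact permutation p = 0.0346) to -3.17 with 1 library left out, and that in the share of the 10 most abundant from -1.05 (without SHR replicate 5, exact permutation p = 0.0260) to -0.339. Between QDG and WKY, miRNAs detected differed by -5.67 with at least 5 reads and by -1 with at least 10 reads (exact permutation p = 0.333 and 0.829), and the share of the single most abundant miRNA by -2.34 (exact permutation p = 0.0390); the cause was not tested. The correlation of SHR against WKY with QDG against SHR was -0.36 to -0.18 with 1 library left out, and 0.01 over called miRNAs with split SHR libraries.

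With the replicate number as a block, 93, 0 and 77 miRNAs and 6, 1 and 5 lists were called in the order above (0 by limma for QDG against SHR). The numbers did not pair the libraries: over 18 pairs with the same number r ran from -0.17 to 0.23, 7 were over 0.1, and 2 of 18 libraries correlated best with their own number. Of 2607 values of named miRNAs under other settings, 2535 stayed on their side of the threshold, 55 lost and 17 gained a call, and of 2124 with 1 library left out 2056, 53 and 15, with 0 called values changing sign. Sizes of change moved more for some miRNAs. Over all alternatives for SHR against WKY, log2 changes ran from 0.74 to 1.73 for miR-190b-5p, 0.39 to 0.93 for miR-132-3p and -1.18 to -0.63 for miR-379-5p. They ran from -1.52 to -0.32 for miR-494-3p and -1.15 to -0.42 for miR-541-5p, while miR-34a-5p kept 0.92 to 1.12. miR-206-3p gained a call with the block between SHR and WKY and between QDG and WKY (limma adjusted p = 0.0203 and 0.0344), and miR-126a-3p gained one under TMM between QDG and WKY (0.0452); a change of sign with no call on either side counted as staying. Depth limits scarce miRNAs: at 0.135 to 0.225 RPM per read, those near 1 RPM rest on few reads.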

Other observations

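The tests of hairpin arms and of neighbouring genes in this part were written before their results were seen, while the splits of the libraries and all miRNAs named here were chosen after the values were seen.

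The 3 tested miRNAs of the miR-183 cluster, known from sensory organs and epithelia and not among the fixed lists, were higher in SHR: miR-96-5p rose by 1.58 ± 0.18 and miR-183-5p by 0.98 ± 0.17 on the log2 scale beside the 1.98 ± 0.18 of miR-182 (SE, limma adjusted p = 6.88e-08, 8.28e-05 and 6.86e-09, higher in 6 of 6 SHR libraries each). miR-184 rose by 1.56 ± 0.22 (adjusted p = 5.5e-06, 6 of 6 libraries) and miR-135a-5p by 0.99 ± 0.28 (adjusted p = 0.0116, 5 of 6 libraries), and miR-298-5p fell, with -1.03 ± 0.19 (adjusted p = 0.000133, 6 of 6 libraries). In a gene neighbourhood that holds miR-322, miR-351, miR-450a, miR-450b, miR-503 and miR-542, 4 of 11 mature miRNAs fell in SHR and 4 in QDG against WKY. In one that holds miR-201, miR-547 and miR-3585, 4 of 6 fell in each comparison. In the pair of miR-34b and miR-34c, 4 of 4 mature miRNAs fell in each, while miR-34a-5p, encoded elsewhere, rose. In the neighbourhoods of miR-17 (6 mature miRNAs) and of miR-143 with miR-145 (4), limma called 0 in each comparison with WKY.

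If a strain acts on miRNA precursors or on shared transcripts, both arms of a hairpin and neighbouring hairpins should move together. Across 126 hairpins with both arms tested, the log2 changes of the arms between SHR and WKY correlated with Pearson's r = 0.723 and Spearman's rho = 0.680 (permutation p = 1e-05, the smallest that 100000 permutations can give), with r = 0.689 without the 2 hairpins farthest from the median, and 100 of 126 pairs shared a sign. Of 145 pairs of hairpins within 10 kb, 77.2% shared a sign, beside 50.6% with hairpins permuted (permutation p = 0.0001, the smallest that 10000 permutations can give), and 69.4% of the 85 pairs outside Dlk1-Dio3 did (permutation p = 0.0027). Hairpins are not independent replicates, and paired arms share library noise, so these values are consistent with changes at the level of precursors, as a hypothesis. RefSeq's GRCr8 names placed 255 of 284 tested hairpins.

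Chance as the source of the calls was examined over 100 of the 462 splits of the 12 libraries compared, the real one included. For SHR against WKY, 1 split, the real one, gave as many as the real 95 miRNAs, the highest other having 37. Chance is thus argued against for that count, but not excluded. Not all splits were drawn, and the cut was set afterwards. The other splits also mix the groups, so the difference between the groups adds to their spread. At least the real 6 lists were called in 4 splits, the highest other having 7. Another split thus called more lists, and the cut was set afterwards, so chance was not excluded for the list count. These are calls at camera's preset correlation, and 0 lists were called with an estimated one. For QDG against WKY, 1 split, the real one, gave as many as 73 miRNAs (highest other 31), which argues against chance for that count with the same limits. As many as the real 5 lists were called in 4 splits (highest other 5), so chance was not excluded for the list count. With an estimated correlation 0 lists were called. For QDG against SHR, a real count of 0 miRNAs is reached by any split, so the 100 of 100 that did decide nothing (highest other 2; 15 at an unadjusted p under 0.05 in limma, and 0 calls by edgeR, DESeq2 and limma-voom). At least 1 list, the real number, was called in 63 splits (highest other 6), so chance was not excluded for the call of the Dlk1-Dio3 list.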
